A study of Euprymna scolopes with 7 samples.

How the data were processed

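Embryos were freed of chorion and yolk and dissociated, per the labels' protocols. For ATAC-seq, an OMNI-ATAC procedure with Tn5 was applied to 6 libraries of 3 pooled embryos, 2 biological replicates at each of 3 stages. For Hi-C, chromatin of 30 pooled embryos at stage 27 was fixed, cut with HindIII, filled in with a biotinylated nucleotide and ligated, and the 1 library was run in 2 lanes. Per the submitters' processing notes, FastQC, Bowtie2 and Genrich were used for ATAC-seq, and HiC-Pro and Bowtie2 for Hi-C. Their settings, whether reads were shifted for the Tn5 insertion, duplicate handling and the genome build are not given in the sources used here.

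The authors called peaks in each ATAC-seq library separately, as the deposited lists are 1 per library. Each deposited peak has a start, an end, a display score from the authors' peak caller, a signal, and the -log10 of a p-value and a q-value at its summit as deposited by the authors. The deposited signal appears to be the caller's area value, from the column layout of its output, and was 20.0 or more in every list. Since heights of separately called lists depend on depth, signal was used only to rank peaks within a list. The authors' deposited Hi-C matrices give a contact signal, balanced by iterative correction as their names state, for pairs of bins of 100, 40 and 20 kb, with pairs without contacts left unlisted. Depth of the ATAC-seq libraries is unknown, so no limit for undetected peaks was derived. A region missing from a list may be open but under the caller's threshold.

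The deposited matrices number their bins. The bins were placed on the 48 scaffold groups by taking the groups in the sorted order of their full names, with the lengths those names state. This placement was checked on the contacts. At all 47 junctions between groups, the contacts crossing within 2 Mb lay below the 5th percentile of other positions at each of the 3 bin sizes (median 6.44 against 1065 at 100 kb). Numeric order of the groups gave a median of 1206 at its junctions. Of the numbered 100 kb bins, 98.0% had contacts.

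Peaks of the 6 libraries were merged where they overlapped by at least 1 bp, and a library was taken to hold a region if it had a peak in it. Similarity was the Jaccard index over regions. A region was restricted to a stage when both its libraries and none of the other 4 held it. Stages were compared by exact permutation over the 15 splits of the libraries into pairs (one-sided for similarity and restricted regions, two-sided for the number and width of peaks), or over 90 labelled assignments for neighbouring stages. Named regions were, per stage, the 8 restricted regions with the highest mean percentile of signal within the library, plus the 5 highest regions found in all libraries, and for Hi-C the 5 boundaries with the lowest insulation. Samples were grouped by the stage in the labels, which call the replicates biological. These rules, the tests and most alternatives were set before the data were examined.

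Contact decay was the slope of log10 mean contact on log10 distance from 200 kb to 5 Mb, with 1000 bootstrap draws of scaffold groups. Insulation was the mean contact between the 5 bins before and the 5 bins after a bin at 100 kb, needing 60% usable pairs, as log2 over the scaffold median. A boundary was a local minimum with a prominence of at least 0.2. Compartments were the first eigenvector of the correlation of observed over expected contacts in scaffold groups of at least 100 usable bins, with the expected pooled to at least 200 pairs and the highest 0.5% of values limited. Peak density at boundaries and its correlation with the eigenvector were tested with 1000 circular shifts within scaffold groups (two-sided for boundaries, one-sided for the absolute correlation). The number of partner bins is the number of bins with which a bin has a listed contact, and densities were scaled by it in 20 classes.

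The procedures were tested on simulated data. With presence redrawn without a stage effect over 42547 regions, 1198 regions were restricted by chance (exact permutation p = 0.867). With 600 planted regions, 83.8% of them drawn as present in both libraries of their stage, 1679 regions were restricted. The p was then 0.0667, the smallest possible. The 83.8% was set by the simulated detection rate and does not score the procedure. Libraries were redrawn by list size alone, without the sharing between pairs of the real lists, so no power for the real lists follows. In 6 simulated scaffold groups of 8202 bins, a slope of -1 was recovered as -0.999, 99.7% of 739 boundaries were found within 1 bin, and the compartment ratio was 0.933 without compartments and 2.45 with them. Peaks planted at 1.5 times the density in boundary bins gave a ratio of 1.45, and 0.998 without planting. They were planted in the same called bins that were then scored, without clustering of peaks. The 1.45 was therefore set by the planting and does not score the placement of boundaries.

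Alternatives were the 50% of each list with the smaller p-values, equal list lengths, scaffolds of at least 1 Mb, a reciprocal overlap of 50%, merging across 500 bp, removal of peaks wider than 5 kb, the Jaccard index by bases, blocks by replicate number, leaving out each library, and other Hi-C bin sizes, windows, prominences and eigenvectors. The location of regions relative to genes, gene lists at restricted regions and GC content were planned only for an assembly and annotation matching the peak positions, and were not analysed here. No gene is therefore named. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.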

Results

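Chromatin accessibility and genome folding were measured in embryos of the Hawaiian bobtail squid, Euprymna scolopes, a cephalopod with a large and rearranged genome. ATAC-seq, in which the Tn5 transposase inserts adapters into open chromatin, was done at 3 embryonic stages (stage 20, stage 24/25 and stage 28/29) with 2 biological replicates each, every library being made from 3 pooled embryos. Hi-C, which records pairs of DNA segments that lie close together in the nucleus, was done on 1 library of 30 pooled embryos at stage 27. The series set out to ask whether and how the reorganisation of the cephalopod genome bears on gene regulation. The peak lists held 36933 and 24472 peaks at stage 20, 23580 and 24290 at stage 24/25, and 28410 and 22443 at stage 28/29, for replicates 1 and 2 in turn. Read depth behind the peak lists is unknown, since the lists give no read numbers. The Hi-C matrix at 100 kb listed 48640875 pairs of bins. Positions are those of the assembly named in the peak lists, whose 48 large scaffold groups, built from 2189 contigs, span 4824 Mb. Its build name is not given in the sources used here, and gene positions on it were not used here.

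No difference between stages in the amount of open chromatin called was detected. Stage 20 had 30703 ± 8811 peaks (SD, n = 2), stage 24/25 had 23935 ± 502 and stage 28/29 had 25427 ± 4219. The peaks covered 12.3 ± 2.49 Mb, 9.95 ± 0.258 Mb and 9.68 ± 1.13 Mb at the 3 stages. Median peak width was 299 ± 21.2 bp, 303.5 ± 0.707 bp and 276 ± 9.90 bp. In exact permutation tests over the 15 splits of the 6 libraries into pairs, p was 0.533 for the number of peaks and 0.333 for both covered length and median width (two-sided; Benjamini-Hochberg adjusted p = 0.64 for each, among 6 measures). The smallest p this design allows is 0.0667, so none of these tests could reach 0.05. Replicate 1 of stage 20 carried the excess of that stage. Without it, the ratio of peak number at stage 20 to stage 28/29 went from 1.21 to 0.962.

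**Figure D1:**
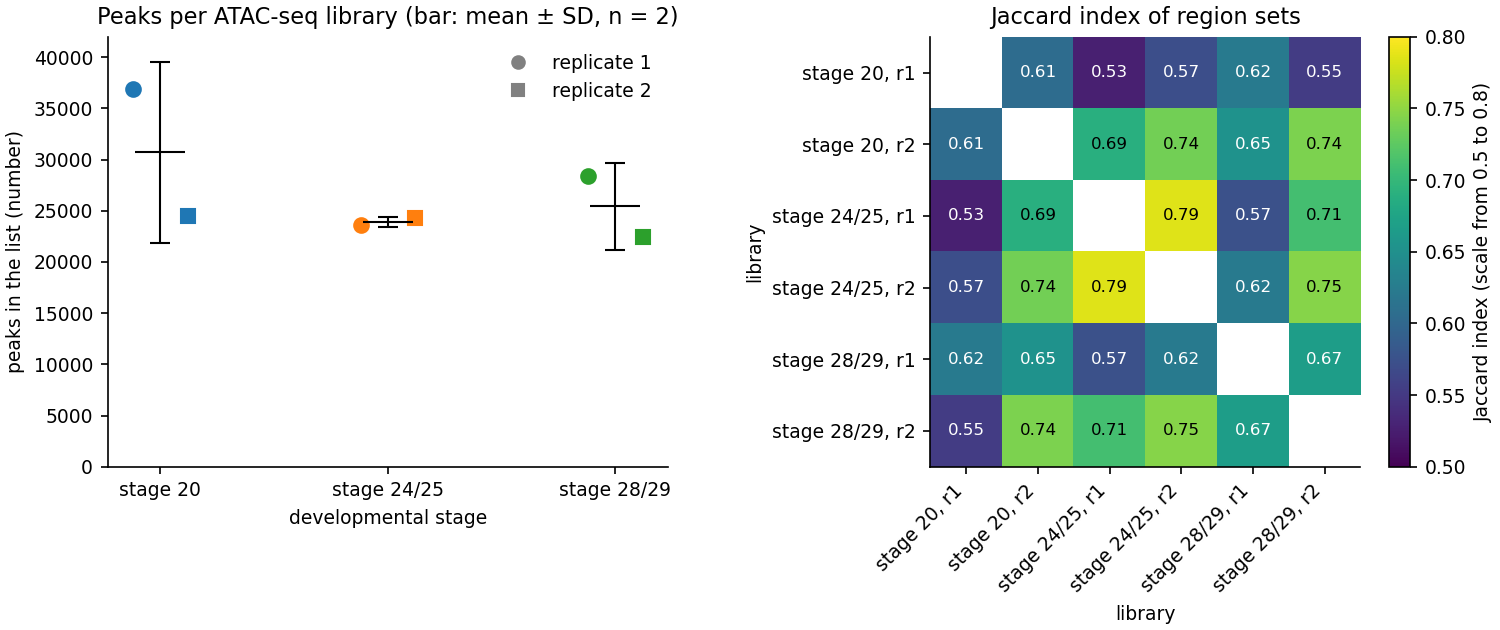
Left, the number of peaks in each ATAC-seq library by developmental stage, with circles for replicate 1, squares for replicate 2 and bars for the mean ± SD (n = 2). Right, the Jaccard index of each pair of libraries (shared regions over all regions of the pair, colour scale from 0.5 to 0.8). The stage 24/25 pair is highest at 0.786, and replicate 1 of stage 20 is at 0.624 or below with every other library.

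A common set of open regions was present throughout the sampled period. Peaks of the 6 libraries merged into 42547 regions, of which 16454 (38.7%) were found in all 6 libraries. The 5 strongest of these lay on scaffold group 14 at 100501424 to 100505261, group 38 at 34882329 to 34886095, group 1 at 177433532 to 177438363, group 3 at 11769898 to 11773372 and group 12 at 88659013 to 88663019. They were 3475 to 4832 bp wide, against a median of 437 bp for regions found in all libraries. A further 11463 regions appeared in 1 library only, and 7270 of them came from replicate 1 of stage 20. The open regions were spread unevenly. Across the 45 scaffold groups of at least 10 Mb, the mean density ran from 3.02 to 7.76 peaks per Mb, with a median of 4.68.

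Libraries of the same stage shared more regions than libraries of different stages, on average, but some other pairings of the libraries gave as large a difference. The Jaccard index of replicates was 0.606 at stage 20, 0.786 at stage 24/25 and 0.667 at stage 28/29. The highest index between stages was 0.745, for replicate 2 of stage 24/25 with replicate 2 of stage 28/29. The mean of same-stage pairs exceeded that of the 12 other pairs by 0.0405 (exact permutation p = 0.267, one-sided, 15 splits). Under the alternative list, overlap and merging rules the exact permutation p was 0.133 to 0.267. Among the 6 pairings that join only libraries of different replicate number, the true one was highest (exact permutation p = 0.167, one-sided, the smallest possible). Each pairing with as large a difference thus joined libraries of the same replicate number. Only the stage 24/25 pair was above every pair of different stages. Without replicate 1 of stage 24/25 the difference became -0.0193, and without replicate 2 of that stage it was 0.00245. Without replicate 2 of stage 20 it was 0.110, the highest of the 15 splits (exact permutation p = 0.0667, one-sided, the smallest possible). The numbering of the deposited lists set the replicate 1 libraries apart from the replicate 2 libraries, so the replicate number may mark a preparation batch. Each such batch holds 1 library per stage and gives no comparison of stages by itself. Libraries of the same replicate number had a mean index of 0.658, against 0.651 for different numbers (exact permutation p = 0.4, one-sided, 10 splits, smallest possible 0.1). The latter pairs include the 3 same-stage pairs, so this comparison mixes stage with replicate number and cannot exclude a batch. Pairs of replicate 2 libraries had 0.736, 0.741 and 0.745, the highest between stages, and pairs of replicate 1 libraries 0.526, 0.624 and 0.574. Of 10 measures per library, 4 differed between replicates 1 and 2 in the same direction at all 3 stages. Replicate 1 had the lower median and 95th percentile of peak width, more regions found in no other library and the higher correlation with the Hi-C eigenvector (exact sign test p = 0.25 each, two-sided, the smallest possible). At that p, some of 10 measures would show a common direction without any effect of replicate number.

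Neighbouring stages were not measurably closer to each other than the earliest and the latest stage. The mean Jaccard index of stage 20 with 24/25 and of 24/25 with 28/29 exceeded that of stage 20 with 28/29 by 0.0040 (exact permutation p = 0.533, one-sided, 90 labelled assignments, smallest possible 0.0222). With lists of equal length the difference was -0.0145.

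Regions with a peak in both libraries of 1 stage and in none of the other 4 libraries were few and weak. There were 864 at stage 20, 550 at stage 24/25 and 127 at stage 28/29. Their median width was 294, 238 and 159 bp, against 437 bp for regions found in all libraries. Single peaks of these stages, before merging, had 299, 303.5 and 276 bp. The median percentile of their signal within a library was 20.7, 18.1 and 13.2 for the restricted regions, against 64.3 for regions found in all libraries. Part of this difference follows from the definition, since absence from 4 thresholded lists favours weak peaks and presence in all 6 favours strong ones. The sum of 1541 was exceeded by other pairings of the libraries, up to 3689 (exact permutation p = 0.267, one-sided, 15 splits). All of these join replicate 1 of stage 20 with replicate 1 of stage 28/29, a pair with 3081 regions of its own. Every other pairing gave a lower sum than 1541. The order of the stages depended on list length. With every list reduced to its 22443 strongest peaks, the counts were 320, 900 and 342. Leaving out a library of a stage removes the need for a second peak there. Without replicate 1 the stage's own count was 1351, 967 and 282 at the 3 stages, and without replicate 2 it was 8169, 1631 and 2254.

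By the mean signal percentile of the 2 libraries, the 8 strongest regions ran from 90.1 to 72.7 at stage 20, from 73.1 to 59.6 at stage 24/25 and from 80.6 to 32.2 at stage 28/29. At stage 20 the first was on the unplaced scaffold ScSUXzt_64503 at 7351 to 8364, with a signal of 1727 and 507 in replicates 1 and 2. The next was on group 22 at 25271901 to 25272593 (984 and 311), followed by group 44 at 9194705 to 9195175 (335 and 566), group 27 at 55959263 to 55959555 (398 and 357), group 28 at 80973904 to 80975058 (1374 and 185), group 37 at 13242855 to 13243624 (983 and 186), group 26 at 59187125 to 59188066 (863 and 163) and the unplaced scaffold ScSUXzt_194857 at 90413 to 91203 (826 and 144). At stage 24/25 the first was on the unplaced scaffold ScSUXzt_9931 at 9637 to 9978 (316 and 293). The others were on group 34 at 38571891 to 38572651 (1179 and 116), group 12 at 28101226 to 28101482 (278 and 206), group 2 at 102946451 to 102946976 (688 and 99.5), group 30 at 39202828 to 39203060 (326 and 145), group 0 at 174206425 to 174206682 (184 and 222), group 4 at 49617834 to 49618041 (200 and 176) and the unplaced scaffold ScSUXzt_340767 at 57661 to 57953 (238 and 140). At stage 28/29 a region on group 14 at 104141179 to 104141457 stood alone, with a mean signal percentile of 80.6 (322 and 427). The next were on the unplaced scaffold ScSUXzt_265674 at 2561 to 2711 and on group 31 at 27413735 to 27413913, with percentiles of 41.7 and 41.0. The others at this stage were on group 15 at 16521018 to 16521170, group 22 at 61245952 to 61246140, group 8 at 132334934 to 132335153, group 17 at 60323882 to 60324074 and the unplaced scaffold ScSUXzt_262062 at 133758 to 133903, with percentiles of 38.6 to 32.2. The signal is the authors' value per peak and ranks peaks only within a list.

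No concentration of the restricted regions on particular scaffold groups was detected. Relative to regions found in all libraries, their distribution over the groups gave a permutation p of 0.552 at stage 20, 0.973 at stage 24/25 and 0.566 at stage 28/29 (10000 draws, Benjamini-Hochberg adjusted p of 0.849, 0.973 and 0.849 over 3 tests).

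In the lists as deposited, more regions had peaks at stage 20 and none at stage 28/29 than the reverse. Of all regions, 1843 had a peak in both stage 20 libraries and in neither stage 28/29 library, and 235 had the opposite pattern, a ratio of 7.84. With equal list lengths the numbers were 753 and 657, a ratio of 1.15. The ratio was 1.85 without replicate 1 of stage 20, 24.8 without replicate 2 of stage 20 and 1.08 without replicate 2 of stage 28/29.

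The pair of libraries with the most regions of its own crossed stages. Replicate 1 of stage 20 and replicate 1 of stage 28/29 shared 3081 regions that no other library had, 3.57 times the 864 of the highest same-stage pair. With equal list lengths this pair held 1343 and the highest same-stage pair 900. Replicate 1 of stage 24/25, of the same replicate number, shared 322 exclusive regions with replicate 1 of stage 20 and 60 with replicate 1 of stage 28/29.

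**Figure D2:**
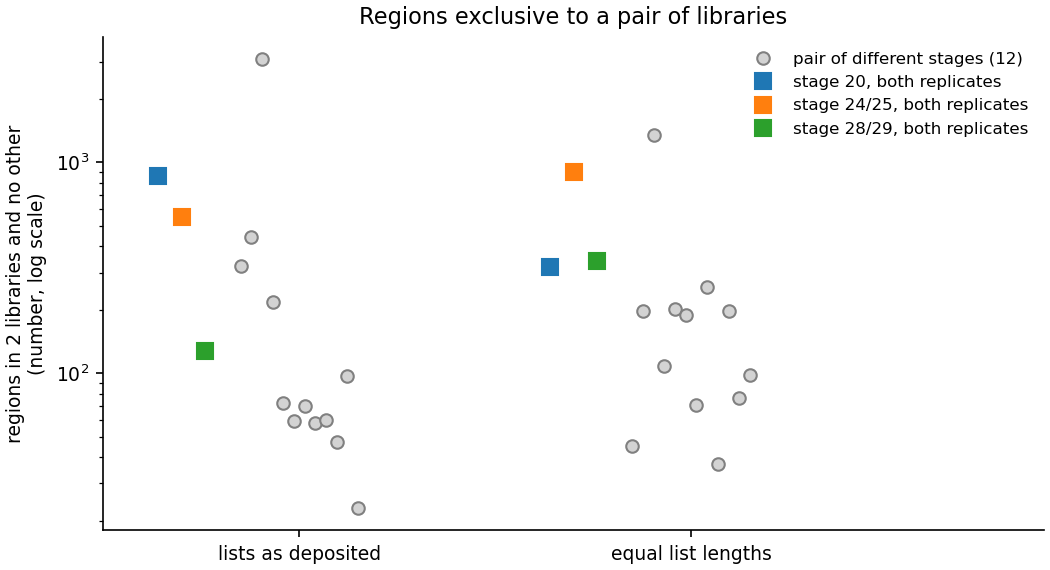
Number of regions (log scale) found in a given pair of libraries and in none of the other 4, for the lists as deposited and for lists of equal length. Squares are the 3 same-stage pairs and grey circles the 12 pairs of different stages; the highest circle, 3081 and 1343, is replicate 1 of stages 20 and 28/29.

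In the stage 27 nuclei, contact frequency fell steeply with distance along the scaffold groups up to about 10 Mb. Beyond that it fell far more slowly, and at 50 Mb it was still above the level between groups. The mean balanced contact of 2 bins of 100 kb was 59.2 at 0.1 Mb, 5.90 at 1 Mb, 0.621 at 10 Mb and 0.363 at 50 Mb. Bins on different scaffold groups had a mean of 0.0303. Of the contacts on scaffold groups, 44.5% joined bins of the same group. From 200 kb to 5 Mb the slope of log10 contact on log10 distance was -0.952, with a 95% bootstrap interval over 45 scaffold groups of -0.968 to -0.936. The Hi-C values come from 1 library and have no replicate check, and the intervals describe scaffold groups within it.

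**Figure D3:**
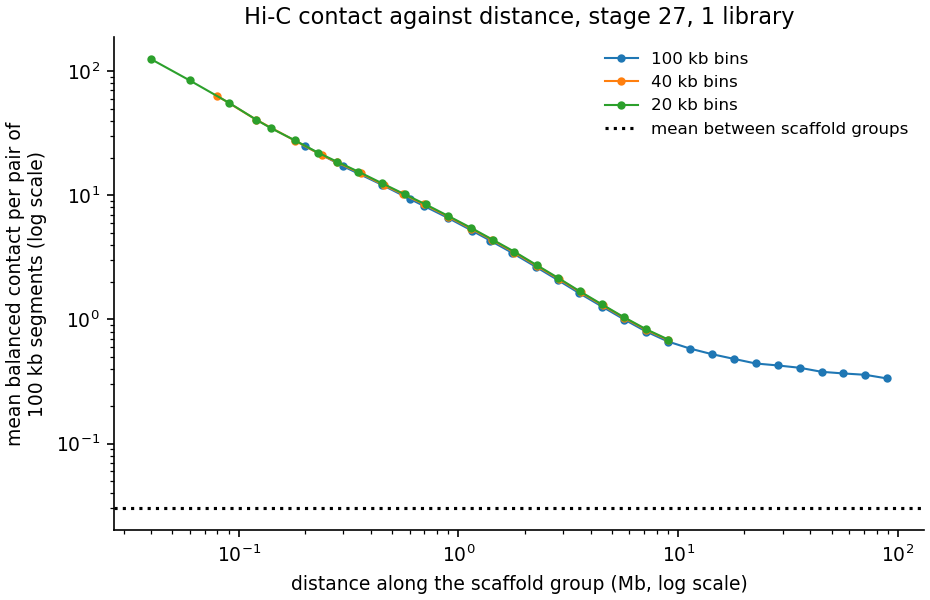
Mean balanced contact per pair of 100 kb segments (log scale) against distance along the scaffold group in Mb (log scale), from bins of 100, 40 and 20 kb. Lines of the 3 bin sizes overlie each other, and at 50 Mb the contact of 0.363 is above the dotted line for contacts between scaffold groups, 0.0303.

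Under the main calling rule, boundaries divided the scaffold groups into domains of about a megabase. At 100 kb, 4181 boundaries were called, with a median spacing of 1.0 Mb (interquartile range 0.7 to 1.4 Mb). Of these, 85.7% had a boundary called from 40 kb bins within 100 kb, against a mean of 22.1% after circular shifts. Both bin sizes hold contacts of the same library, with windows of nearly equal length, so this agreement is no independent check. Matrices without boundaries were not simulated. The number depended on the calling rule, with 2536 boundaries under a 10-bin window and 6299 under a 3-bin window. The 5 boundaries with the lowest insulation lay on group 25 at 60800001 to 60900000, group 4 at 162300001 to 162400000, group 11 at 2300001 to 2400000, group 0 at 18900001 to 19000000 and group 33 at 57300001 to 57400000. Their log2 insulation scores were -10.02, -9.34, -9.29, -9.13 and -9.03. The mean contact across each was 0.326 to 0.719 times that between different scaffold groups. At the median boundary it was 193 times the between-group value. Boundaries per Mb rose with contigs per Mb across 45 scaffold groups (Spearman's rho = 0.579, permutation p = 5e-05, adjusted p = 2e-04; Pearson's r = 0.397, permutation p = 0.0118, adjusted p = 0.0118; two-sided, Benjamini-Hochberg over 4 correlations; r = 0.652 without the 2 groups farthest from the median of contigs per Mb).

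Bins of a scaffold group separated into 2 sets that preferred contacts with their own kind, the pattern known as A and B compartments. Contacts within the outer 20% of bins at either end of the first eigenvector were 3.46 times those between the ends, and ranged from 2.38 to 5.28 over 45 scaffold groups. After circular shifts of the eigenvector the ratio averaged 1.00 and reached 1.08 at most. The eigenvector came from the same contacts, so these shifts do not show which structure it follows. With an eigenvector from odd columns and contacts of even bins, chosen after the data were seen, the ratio was 3.26. The first eigenvector accounted for a median of 4.62% of the variance, and runs of bins of 1 sign had a median length of 0.4 Mb. The longest run, 123.9 Mb on group 0, held 60.8% of that group's bins, and no other group had a run over 50%. The second eigenvector gave a ratio of 2.42.

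In the main planned test, no enrichment of ATAC-seq peaks was detected in the boundary bins themselves, but this call depended on the scaling described below. The density of peaks in 4173 boundary bins was 1.01 ± 0.00957 times that of all scored bins (SD over 6 libraries), and the circular-shift permutation p of single libraries ran from 0.334 to 0.984 (two-sided). For stages in this ratio the exact permutation p was 0.533 (15 splits), where 0.0667 is the smallest possible. When the bins on either side were counted as well, the ratio was 1.11, with a permutation p of 0.0010 in every library, the smallest 1000 shifts can give. Densities in boundary bins were below those of the adjacent bins in all 6 libraries. Across the 4088 boundaries with both neighbours in use, the mean was 5.10 peaks per Mb in the boundary bin and 6.02 in the adjacent bins, a ratio of 1.18 (95% bootstrap interval 1.1 to 1.26). Boundary bins also had contacts with fewer other bins, a median of 1834 against 1904 beside them, and peak density rose with that number, from 1.73 peaks per Mb in the bins with the fewest partner bins to 21.5 in those with the most. With each bin's density divided by that of bins with a like number of partners, the density ratio of boundary bins was 1.09 (largest permutation p of a library 0.0420). Counted with their neighbours, they also gave 1.09 under this scaling (permutation p = 0.0010 in every library), so the ratio was not particular to the boundary bin. The scaling was chosen after the data were seen.

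**Figure D4:**
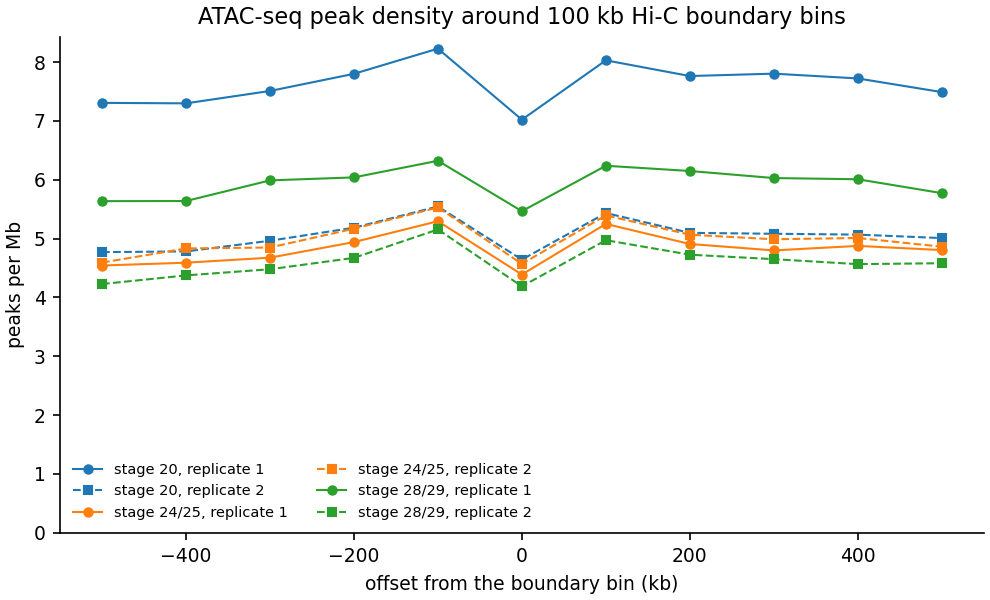
ATAC-seq peaks per Mb against the offset in kb from the Hi-C boundary bin, 1 line per library, with colours for stages, circles for replicate 1 and squares for replicate 2. In every library the boundary bin is below the bins 100 kb to either side, for example 7.02 against 8.23 and 8.03 in replicate 1 of stage 20.

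Peak density followed the compartment pattern weakly, in every library. The absolute Spearman correlation of peak number with the eigenvector across bins within scaffold groups averaged 0.0842 and ranged from 0.0646 to 0.116. Circular shifts gave 0.0438 to 0.0453 on average, and the one-sided permutation p was 0.0010 in each of the 6 libraries, the smallest possible. Bins are not independent replicates. Replicate 1 of stages 20 and 28/29 had the highest correlations, 0.116 and 0.111. For stages the exact permutation p was 0.533 (15 splits, smallest possible 0.0667). In each scaffold group, the peak-rich end was the one toward which peak number rose, by the mean correlation over the 6 libraries. Density was 6.52 ± 1.42 peaks per Mb in the peak-rich 20% of bins and 4.55 ± 0.777 in the opposite 20% (SD, n = 6). The ratio was 1.43 ± 0.0765, and it lies above 1 in part because the ends were named by these same peaks. Regions restricted to stage 20 were in the peak-rich bins in 27.7% of cases (Wilson 95% interval 24.7 to 31), those of stage 24/25 in 24.9% (21.3 to 28.9) and those of stage 28/29 in 24.8% (17.6 to 33.6), against 26.1% (25.4 to 26.8) of the regions found in all libraries. In the opposite bins the shares were 15.2% (12.9 to 17.9), 19.9% (16.6 to 23.6) and 22.0% (15.3 to 30.7), against 18.6% (18.0 to 19.3). The lower share of stage 20 regions in the opposite bins had a p of 0.0158 and an adjusted p of 0.0951, and the adjusted p of the other 5 comparisons was 0.682 to 0.827 (two-sided Fisher's exact tests, Benjamini-Hochberg over 6 tests). These tests and intervals count regions as independent, which regions of the same bin are not.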

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

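Chosen after the data were seen were the comparison of lost with gained regions, the omission of both replicate 1 libraries, the scaling by partner bins, the held-out eigenvector, the omission of the scaffold group with a long eigenvector run, the omission of libraries for peaks at boundaries and compartments, and equal list lengths for peaks and compartments. Of 127 values under alternatives, 83 kept their direction, their side of the threshold or their size, 35 moved, 7 reversed and 2 passed the threshold. Tests over the 15 splits could not pass it in this design, so keeping their side says nothing about stability.

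Taking the 50% of each list with the smaller p-values gave 823 restricted regions, 479, 273 and 71 at stages 20, 24/25 and 28/29, as fewer peaks entered. Equal list lengths gave 320, 900 and 342, a ratio of lost to gained regions of 1.15 and a neighbouring-stage difference of -0.0145. Reciprocal overlap gave 288 regions at stage 28/29. Without both replicate 1 libraries of stages 20 and 28/29 there were 4729 (2395, 1326 and 1008), since fewer libraries can exclude a region and stages 20 and 28/29 then need 1 peak only.

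Over the omission of single libraries, restricted regions ran from 2168 to 8982 (1028 to 8169, 633 to 1631 and 148 to 2254 by stage) and the lost to gained ratio from 1.08 to 24.8. The peak number ratio of stage 20 to 28/29 ran from 0.962 (without replicate 1 of stage 20) to 1.45, the same-stage Jaccard difference from -0.0193 (without replicate 1 of stage 24/25) to 0.110, and the neighbouring-stage difference from -0.0236 to 0.0318. The last was -0.0085, -0.0179 and -0.0236 without replicate 1 of stage 20, replicate 2 of stage 24/25 and replicate 2 of stage 28/29. The cause was not tested.

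The decay slope was -1.0 from 500 kb to 10 Mb. Boundaries numbered 2754 at a prominence of 0.5, 6299 with 3-bin and 2536 with 10-bin windows. The second eigenvector gave 2.42, and an eigenvector from odd columns with contacts of even bins gave 3.26. Peak density at boundaries was 1.11 with the 2 neighbours, 1.09 after scaling by partner bins and 0.991 for the stricter lists, and the cause was not tested.

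Replicate numbers were not taken to pair the libraries (correlations of replicate differences -0.0136, 0.121 and -0.0421, and -0.0263, 0.230 and -0.0330 with equal list lengths). With the replicate block, values stayed at 1.21, 0.0405, 1541 and 0.0040, with exact p of 0.5, 0.167, 0.167 and 0.556. The smallest possible are 0.167, 0.167, 0.167 and 0.0556, so no call could change. Within the block the 1541 restricted regions of the true matching were the highest of the 6, the next having 1008. Equal list lengths give no value for the number of peaks. Alternatives for gene location, gene lists and GC content were not run. Unknown read depth limits every comparison of list lengths.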

Other observations

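Peak density varied along the genome. Of 4806 windows of 1 Mb, 74 held no peak in any library, and the median window held 3.5. The densest window was on scaffold group 7 at 62000001 to 63000000, with 48.2 ± 2.93 peaks (SD, n = 6), followed by group 19 at 17000001 to 18000000 with 40.5 ± 5.50. Contacts between scaffold groups also followed the ends of the eigenvector. These ends were matched across groups by peak number, as peak-rich or opposite. Contacts of like ends of the eigenvector on different groups were 1.13 times those of unlike ends, against 0.995 to 1.01 over 99 circular shifts (permutation p = 0.01, the smallest possible). Peak density also rose with the number of partner bins, and whether that gives this ratio was not tested.

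The tests on the eigenvector ends, on boundaries without a missing bin, on boundary prominence and on scaling by partner bins were chosen only after the results were seen. The scaling was added once the planned test of partner bins had fallen between its bounds. A further reading was tried then too: among the 1758 boundaries with at least as many partner bins as their neighbours, the ratio of peak density beside the boundary to that in it was 0.805 (95% bootstrap interval 0.739 to 0.875), and among the 2330 others it was 1.56. Since peak density follows the number of partner bins, this split by itself moves the ratio, and it decides nothing. Regions found only in replicate 1 of stage 20 lay in the peak-rich bins in 22.5% of cases, and those found only in replicate 1 of stage 28/29 in 30.0%. The eigenvector ends were named first by the correlation of peak number with the eigenvector in all 6 libraries, then by that correlation in the other 4 libraries, and last by which outer 20% of bins held more peaks of those 4.

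Replicate 1 of stages 20 and 28/29 shared more exclusive regions than any same-stage pair. Unequal list lengths stayed open, since at equal lengths the pair's count went from 3.57 to 1.49 times that of the highest same-stage pair (bounds set in advance 1 and 1.5), and so did weak peaks, with a median signal percentile of the exclusive peaks of 36.6 (bounds 25 and 50). In the peak-rich bins lay 35.9% of the exclusive regions, but the ends had been named with these regions included, and with the ends named by the correlation in the other 4 libraries the share was 29.4% (Wilson 95% interval 27.8 to 31.1) against 26.9% (26.2 to 27.6) of regions in all libraries (two-sided Fisher's exact p = 0.00552). That test counts regions as independent, which regions of the same bin are not. The regions in all libraries, unlike the exclusive ones, also took part in naming the ends. With the ends named by the outer bins the excess was 0.626 percentage points, against -4.59 to -0.313 for 95% of circular shifts (permutation p = 0.0090, two-sided), so its size depends on the naming and this end stays open. A preparation shared by the replicate 1 libraries was looked at only through replicate number, where replicate 1 of stage 24/25 shared 45 and 37 exclusive regions with these libraries at equal lengths, and a preparation or embryo property of these libraries alone was not tested.

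Some Hi-C boundaries may be joins of the assembly. Boundaries per Mb rose with contigs per Mb (rho = 0.579), and 29 boundaries had contacts across them of at most 2 times the between-group level. The rise was seen at prominence of 2 or more (rho = 0.505) and under 1 (rho = 0.412; adjusted permutation p = 9.6e-04 and 0.0070), so it was not particular to deep boundaries. Contigs per Mb were 0.334 on group 0 of 204 Mb and 1.56 on group 44 of 15.4 Mb. The correlation does not separate contig number from group length. Contig joins within groups number 2141, fewer than the 4181 boundaries, so 1 boundary per join would leave others. Bins missing from the balancing cannot be the cause of most boundaries, as 94.9% had none in their insulation window, and for the 2.97% with a missing bin within 2 bins (1.98% after shifts, a ratio of 1.50) the cause stays open. No biological explanation was tested.

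Peak density was lower in boundary bins than beside them. In the planned test, partner bins in boundary bins were 0.963 times those beside them (95% bootstrap interval 0.950 to 0.974), between the bounds of 0.9 and 1, which left fewer read pairs open as a cause. In the test added afterwards, scaling by partner number took the ratio of neighbours to boundary bin from 1.18 to 1.03 (0.961 to 1.11), so density that follows the partner number may account for the dip, though open chromatin could itself raise that number. Contig joins stayed open, as the ratio at prominence under 1 exceeded that at 2 or more by 0.177 (-0.0083 to 0.352). No biological explanation was tested.

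A hypothesis set before its test was that restricted regions of 1 stage cluster along the genome. Of neighbouring restricted regions in the same domain, 51.4% were of the same stage, against 45.2% with permuted labels (permutation p = 0.0100, one-sided, 10000 draws). Labels were permuted over regions, which are not replicates of a stage. Each label stands for 1 pair of libraries, so a local property shared by 2 libraries could give the same excess. Pairs of libraries of different stages were not tested in this way. Whether domains matter beyond distance stayed open, as neighbours within 1 Mb were of the same stage in 54.0% of pairs within a domain and 48.7% across a boundary (two-sided Fisher's exact p = 0.321), and the latter lay farther apart (median 614 against 198 kb).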
